A study of Mus musculus with 6 samples.

How the data were processed

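Total RNA of C2C12 mouse myoblasts was prepared with an RNeasy kit, labelled and hybridised to Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. The 6 arrays fall into 3 silenced and 3 control samples by their titles, which also give the replicate numbers 1 to 3. The deposited values are log2 signals per probe set made with the robust multi-array average (RMA) in Expression Console, per the submitters' processing notes. Per the file headers, engine version 1.3.1.187 corrected the background, quantile-normalised the perfect-match probes of the 6 arrays together, summarised each probe set by median polish and wrote log2 values to 2 decimals. Quantile normalisation gives the probes of all arrays 1 distribution, so a shift of most transcripts in the same direction would be removed. The genome build is not given in the sources used here, and no coordinates are printed. A second deposited table holds the same log2 values, with a largest difference of 0 from the first, and was used only to check this.

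Of 41345 probe sets, 23521 carried 1 gene symbol in the platform annotation, 1820 carried several and 16004 were not listed in it. The 25341 listed probe sets were tested, and genes are named only from probe sets with 1 symbol. Of those, 23328 matched a gene of the reference table (assembly GRCm38.p6) by Entrez identifier, and 0 symbols changed. For gene lists each of 22180 genes was represented by the probe set with the highest mean signal over all arrays.

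Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior) on the deposited values, silenced minus control, with no covariate. Adjusted p values are Benjamini-Hochberg values over all tested probe sets, two-sided, with a threshold of 0.05. SE is limma's moderated standard error, SD the spread between the 3 arrays of a group, and a fold is taken from the difference of mean log2 values. Of 51 gene lists fixed in advance, those with at least 5 measured members were tested, which left 50. The list of proteins encoded by mitochondrial DNA had 0 measured members. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, whose directional test asks whether the members of a list move one way on balance, were alternatives. Some lists share genes. The median, mean and tested direction of a list differ in sign in the lists of smooth muscle and cytoskeletal targets, endoplasmic reticulum chaperones, cell cycle inhibitors, epithelial-mesenchymal transition factors and neural and epithelial markers, none of which was called.

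Named genes follow a rule set before the data were examined. It takes Cox4i1 and Cox4i2, the 10 largest rises and 10 largest falls among called probe sets with 1 symbol and no overlap between the groups, and from each list up to 4 called members with the largest change, or up to 2 where none was called. Predicted genes were skipped, 2 among the rises and 0 among the falls. Array precision is limited by the number of arrays, and no detection calls were used here. As a substitute chosen after the results were seen, a named gene's signal counts as within background if it lies at or under the 95th percentile of 1405 olfactory and vomeronasal receptor probe sets in the same array. The labels give a lower limit of RNA integrity whose last digits count up from sample to sample in the deposited order, as a filled column would, and it was not used.

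The fit was tested on simulated data with the real means and spread of the 25341 probe sets, with 200 of them changed. Of 100 changed by 1 log2 it recovered 30, and of 100 changed by 2 log2 it recovered 85, with 5 false among 120 calls. Those rates may not carry over to the real arrays, where the spread was uneven between arrays. The SD of differences from the mean of the other arrays was 0.736 in silenced replicate 3, against 0.302 to 0.398 in the rest. In 51 simulated lists camera called the shifted list and 0 of the 50 unchanged ones, but there the genes were independent. Alternatives covered the normalisation, dim probe sets, the variance model, array weights, the probe sets tested, the threshold, the test and the list test. They also covered the replicate number as a block and each array left out. Their plan had 36 entries, set before the data were examined, and 1 setting could serve several results. A further 4 were added after silenced replicate 3 was seen to stand apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.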

Results

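RNA of C2C12 cells, a mouse myoblast line that can fuse into muscle fibres, was measured on 6 gene expression arrays. In 3 samples the gene of subunit IV isoform 1 of cytochrome c oxidase, the terminal enzyme of the mitochondrial respiratory chain, had been silenced, and 3 samples were controls. The study's title places the comparison in the context of a shift of metabolism towards glycolysis after loss of this enzyme. Cells were taken while growing at 70% confluence in medium with 10% serum. The medium of the silenced cells also held 1 mM pyruvate and 50 µg/ml uridine, so that silencing and these additions cannot be separated. The labels describe 3 independent samples a group and do not say whether these were separate cultures, so the p-values measure only the spread between these samples. The number of arrays limits the precision of each value.

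The silenced gene itself, Cox4i1, was lower in the silenced arrays, at log2 signals of 7.42, 7.38 and 10.47 in silenced replicates 1, 2 and 3 against 11.84, 11.67 and 11.74 in control replicates 1, 2 and 3. The mean difference was -3.33 (SE 0.81, n = 3 and 3), or 10.0-fold lower, with a limma adjusted p of 0.058, which missed the threshold of 0.05. The miss came with silenced replicate 3, whose Cox4i1 signal lay 1.28 log2 under the control mean, recorded as a difference of -1.28. Without that array Cox4i1 fell by 4.35 on the log2 scale (SE 0.079, 20.4-fold, adjusted p = 1.1e-06). Its isoform Cox4i2, which is best known from lung, had means of 8.09 ± 0.10 in silenced and 7.96 ± 0.19 in control arrays (SD, n = 3 each), a difference of 0.14 with an adjusted p of 0.64.

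Silenced replicate 3 stood apart from the other 5 arrays in its other genes as well. Its Pearson correlation across named probe sets was 0.940 with silenced replicate 1 and 0.936 with silenced replicate 2, against 0.997 between those replicates and 0.996 to 0.997 among the controls. The SD of its log2 values was 1.90, against 2.16 to 2.21 in the other arrays. On the first principal component, which held 58.3% of the variance, it scored 97.1, and the other arrays lay between -27.4 and -8.54.

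**Figure D1:**
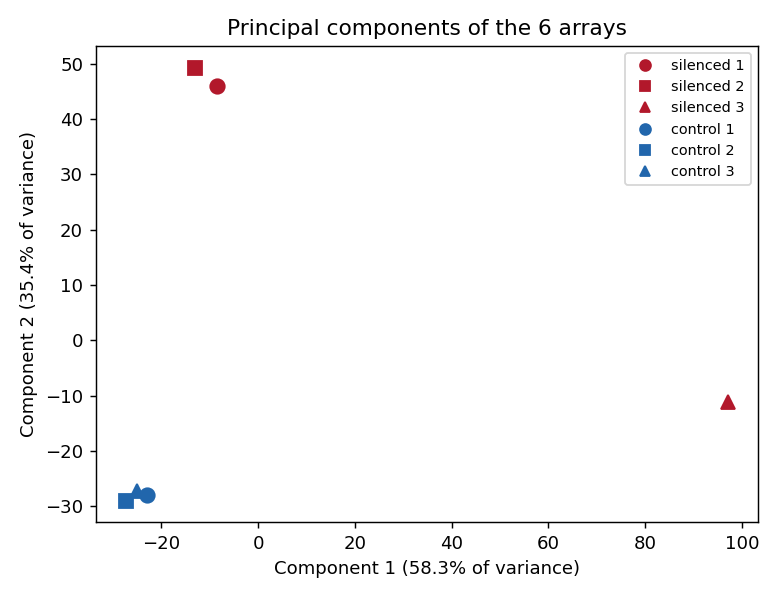
Scores of the 6 arrays on principal components 1 and 2 of the log2 values of 25341 named probe sets, with 58.3% and 35.4% of the variance; red marks are silenced and blue marks control arrays, and the shape gives the replicate number. Silenced replicate 3 lies at 97.1 on component 1, while silenced replicates 1 and 2 part from the controls on component 2, at 46.0 and 49.3 against -29.0 to -27.2.

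Between silenced and control cells, 2229 of 25341 named probe sets (8.8%) differed at an adjusted p under 0.05 in limma, of which 809 rose and 1420 fell. They stood for 1957 genes where a probe set names 1 gene. At least 2-fold changes were found for 745 of them, 239 higher and 506 lower. At an unadjusted p under 0.05 there were 5676, and in 7829 probe sets the 3 silenced values lay wholly above or below the 3 control values, against 10% of probe sets by chance. Without silenced replicate 3 the count was 9247 (36.5%), with 4989 that rose and 4258 that fell. All 2229 were among these, with the same direction. Leaving out control replicate 1, 2 or 3 instead left 3, 5 and 6 probe sets, and leaving out silenced replicate 1 or 2 left 458 and 980. With each array centred on its median, 412 rose and 1165 fell, a lower share of rises than in the deposited values.

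With all 6 arrays the largest rise among called genes was in Slc6a15, a transporter of neutral amino acids, which was 10.3-fold higher, with a log2 change of 3.36 (SE 0.62, adjusted p = 0.025). The membrane protein genes Tmem176b and Tmem176a rose by 3.32 and 3.16. Capn6, a calpain without protease activity, rose from 7.78 ± 0.072 to 10.9 ± 0.23 (SD, n = 3 each), and Bmp4, a ligand of the TGF-beta superfamily, from 7.80 ± 0.30 to 10.9 ± 0.34. Then came Col12a1, a fibril-associated collagen (2.96), Sfrp2, a secreted modulator of Wnt signalling (2.81), the carbonic anhydrases Car2 (2.51) and Car3 (2.47), and Nid2, a basement membrane nidogen (2.43). In this group silenced replicate 3 was 1.82 above the control mean for Slc6a15, against a log2 difference of 4.14 without that array, whereas for Col12a1 it was 3.70 above, against 2.59. Tmem176b, Tmem176a and Car2 were 4.03, 4.07 and 3.20 higher without it. The control signals of Slc6a15 (5.31 to 5.68) and its signal in silenced replicate 3 (7.27) lay within the range of receptor genes described below. Its rise is therefore a lower limit in silenced replicates 1 and 2 and not resolved in silenced replicate 3.

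With all 6 arrays the largest recorded fall was in Nefl, the light chain of neurofilaments, at 18.7-fold lower (log2 change -4.23, SE 0.38, adjusted p = 0.0048). Gtpbp10, a GTP-binding protein of mitochondrial ribosome assembly, fell by 3.72 (SE 0.70, adjusted p = 0.027), and the serine protease gene Tmprss11f had a change of -3.65 (SE 0.16). Gzmd, a granzyme, fell by 3.21 and Serpinb9b, of a family of protease inhibitors, fell by 3.07. Mylpf, the fast skeletal regulatory myosin light chain, had a change of -3.16, Tagln, which binds actin in smooth muscle, of -3.13 and Acta1, skeletal alpha-actin, of -3.01. Ccdc73 (-2.89) and S1pr3, a receptor of sphingosine 1-phosphate (-2.58), completed the 10. The order changed without silenced replicate 3, where Gtpbp10 was at -4.57, Tagln at -3.97 (15.6-fold) and Nefl at -3.76 (13.6-fold). In Gtpbp10, Tmprss11f, Gzmd, Mylpf, Ccdc73 and S1pr3 all 3 silenced signals lay within the range of olfactory and vomeronasal receptor genes, which these cells should not express and whose 95th percentile was 6.8, 6.8 and 8.0 in silenced replicates 1, 2 and 3. Those signals may be background, so the differences of these 6 genes are lower limits. Neither their order nor their place against Nefl is resolved. The signals of Nefl (6.37) and Acta1 (7.70) in silenced replicate 3 lay within that range too.

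**Figure D2:**
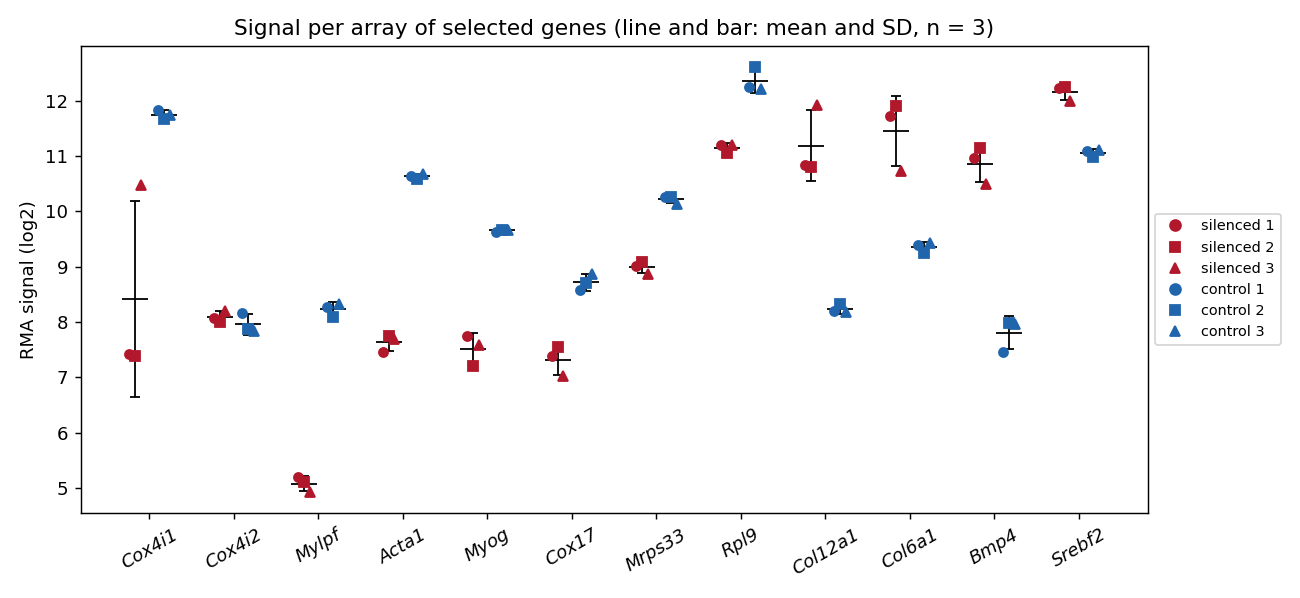
Log2 signal per array (vertical axis) of 12 genes, with silenced arrays in red, control arrays in blue, the mark's shape giving the replicate number, and a black line and bar for the mean and SD (n = 3). Cox4i1 in silenced replicate 3 lies at 10.47, between the other silenced arrays at 7.42 and 7.38 and the controls at 11.67 to 11.84, whereas Acta1, Myog and Mylpf lie lower in each silenced array than in each control.

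Of 50 gene lists fixed before the data were examined, 14 differed from other genes with camera at a preset correlation of 0.01, 4 towards higher and 10 towards lower signal in silenced cells. With the correlation estimated from the data camera called 0 of the 50 lists (7 at an unadjusted p under 0.05). Fry called 13 lists, 9 of the 14 and 4 others (adipocyte markers, lysosomal genes, interferon-stimulated genes and other antioxidant enzymes), and missed 5 of the 14, the mitochondrial ribosomal proteins (adjusted p = 0.13), complexes II and III (0.061), assembly factors (0.24), mitochondrial chaperones (0.43) and mitochondrial biogenesis (0.62). The 9 other ways to split the 6 arrays into 3 and 3 called 13 to 19 lists. The number of list calls therefore does not set the real grouping apart, and the counts of genes below come from the per-gene test. Lists with an estimated correlation near the preset 0.01 also lost their call, so the value of the correlation is not the only difference. Among them were cytochrome c oxidase subunits (0.02) and other matrix proteins (-0.014), at camera adjusted p = 0.32 and 0.35 with an estimated correlation. More members were called without silenced replicate 3 in 48 of the 50 lists. Of all named probe sets 36.5% were then called, against 8.8% with all 6 arrays. A gain in called members is therefore no trait of a list, and such counts below are to be read against that share. For genes named below, the silenced signals of Actc1, Casq2 and Tslp lay within the range of receptor genes in all 3 arrays, so their differences are lower limits. The control signals of Col11a1, Slc16a7, Vldlr, Fas, Rsad2, Cebpa and Cdh5 lay there in all 3 arrays. Their signals in silenced replicate 3, where the range is higher, lay there too, as did those of Slc16a7 and Cdh5 in silenced replicate 1. The size of these differences is therefore not resolved, and for Cdh5 no change was shown (limma adjusted p = 0.51). Slc2a12, Lyz2, Phex and Pecam1 lay within the range in all 6 arrays and are not shown to be expressed. In silenced replicate 3 alone, the signals of Cox7c, Cox17, Pet100, Uqcrq, Ssbp1, Polg2, Rpl5 and Rps27 lay within the range. Those of Myog, Hey1, Tigar, Prdx4, Krt19, Irf9 and Bad did so too. The size of the differences of these genes is not resolved in that array.

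Of 35 measured genes of muscle differentiation 14 fell and none rose (17 lower and 0 higher at an unadjusted p under 0.05). Adjusted over the list alone, 17 fell. Besides Mylpf and Acta1, Myog, the transcription factor myogenin, fell by 2.14 (SE 0.16, adjusted p = 0.0039) and Actc1, cardiac alpha-actin, by 2.09. The list's median change was -0.41 (camera adjusted p = 2.6e-10; adjusted p = 0.32 with an estimated correlation). Without silenced replicate 3, 21 fell and 2 rose. The list of myoblast and satellite cell genes went both ways, with 3 of 21 higher and 2 lower (camera adjusted p = 0.52). In it the Notch targets Hey1 and Hes1 fell by 2.14 and 1.14, whereas Sdc3 (1.24) and Met (0.91), a syndecan and the receptor of hepatocyte growth factor, rose. Among smooth muscle and cytoskeletal targets of SRF, Tagln fell and Vcl, vinculin, rose by 1.02, and 16 of 18 did not pass the test. That list's median was 0.038 and its mean -0.34, so they differ in sign (camera adjusted p = 0.95).

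Nuclear genes of the respiratory complexes fell in part. Of 77 measured members of 4 lists, 25 fell and 0 rose, while 52 did not pass the test. Without silenced replicate 3, 50 fell and 5 rose. For cytochrome c oxidase, 4 of 17 subunit genes fell (7 lower and 0 higher at an unadjusted p under 0.05), among them Cox7c (-0.93, SE 0.17), Cox5b (-0.65), Cox7a2 (-0.63) and Cox5a (-0.55), with camera adjusted p = 0.0011 and adjusted p = 0.32 with an estimated correlation. Of complex I 10 of 32 fell, led by Ndufa7 (-1.27) and Ndufa11 (-1.21), with camera adjusted p = 8.9e-10 and adjusted p = 0.50 with an estimated correlation. Of the list of complexes II and III 5 of 13 fell, with Sdhd at -1.02 and Uqcrq at -0.91. Among the 5 was Cycs (-0.58), cytochrome c, an electron carrier that is not a subunit of either complex. The list had camera adjusted p = 0.00042, and adjusted p = 0.75 with an estimated correlation. Of ATP synthase 6 of 15 fell, with Atp5e at -1.52 and Atp5g3 at -0.92, with camera adjusted p = 1.8e-05 and adjusted p = 0.32 with an estimated correlation. Adjusted over the list alone, 6, 18, 6 and 11 members of these lists fell, and 1 member each of the complex I and the complex II and III list rose. The mean change of the list of cytochrome c oxidase subunits was -0.47 and its median -0.34. Cox4i1, the silenced gene, encodes such a subunit, and its weight in this list was not tested.

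Assembly factors of cytochrome c oxidase fell in 4 of 18 cases and rose in 0 (6 lower at an unadjusted p under 0.05). They were the copper chaperone Cox17 (-1.40, SE 0.17, adjusted p = 0.0093), Pet100 (-1.29), Coa3 (-1.09) and Cox16 (-0.94). The list had camera adjusted p = 0.0036, and adjusted p = 0.92 with an estimated correlation. Of mitochondrial chaperones and proteases, 3 of 15 fell, namely Phb2 (-0.68), Clpp (-0.66) and Htra2 (-0.57), with camera adjusted p = 0.022 and adjusted p = 0.92 with an estimated correlation. Of genes of mitochondrial biogenesis and DNA maintenance, 3 of 17 fell, namely Ssbp1, which binds single-stranded mitochondrial DNA (-1.86), Tfb1m (-0.70) and Polg2 (-0.64), with camera adjusted p = 0.042 and adjusted p = 0.92 with an estimated correlation. These 3 lists rested on silenced replicate 3, where their medians lay at -0.80, -0.69 and -0.67 against the control mean. In silenced replicate 1 the medians were -0.22, -0.020 and 0.0067, and without silenced replicate 3 the camera adjusted p values were 0.30, 0.71 and 0.80. Their members then went both ways, with 6, 4 and 5 that rose and 6, 6 and 7 that fell.

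Of 46 measured mitochondrial ribosomal proteins 11 fell and 0 rose (30 lower and 0 higher at an unadjusted p under 0.05), led by Mrpl11 (-1.39, SE 0.32), Mrps33 (-1.23, SE 0.11), Mrps10 (-1.16) and Mrpl18 (-1.14). The median of the list was -0.69, with camera adjusted p = 8.8e-14 and adjusted p = 0.77 with an estimated correlation. Its median was -1.20 in silenced replicate 3 and -0.44 and -0.43 in silenced replicates 1 and 2, and without silenced replicate 3, 30 fell and 1 rose. Of 39 cytosolic ribosomal proteins 13 fell and 0 rose (25 lower and 0 higher at an unadjusted p under 0.05). They included Rpl9 (-1.21, SE 0.14, adjusted p = 0.0087), Rpl5 (-1.19), Rps27 (-1.05) and Rps7 (-0.97). That list had a median of -0.55, camera adjusted p = 1e-12 and adjusted p = 0.35 with an estimated correlation. Adjusted over the list alone, 20 and 22 members fell. Ribosomal protein genes have many near-identical processed copies, which probes can share.

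Of 23 collagen genes 7 rose and 0 fell (11 higher and 0 lower at an unadjusted p under 0.05), with Col12a1 first, followed by the collagen VI chains Col6a1 (2.10, SE 0.31, adjusted p = 0.013) and Col6a2 (1.73) and by Col11a1 (0.94). The median was 0.67, with camera adjusted p = 5.7e-06 and adjusted p = 0.44 with an estimated correlation, and 17 rose without silenced replicate 3. In that replicate the list's median lay 0.22 above the controls, against 0.81 and 0.85 in silenced replicates 1 and 2. Of 28 other matrix proteins 6 rose and 2 fell, with Nid2, the crosslinking enzymes Loxl1 (1.22) and Lox (1.05) and Thbs1, thrombospondin 1 (0.98), in the lead (camera adjusted p = 0.022; adjusted p = 0.35 with an estimated correlation), and 15 rose and 5 fell without silenced replicate 3. In the TGF-beta list 4 of 23 rose and 2 fell (camera adjusted p = 0.42). Tgfbr2, a receptor, rose by 1.23 (SE 0.14) and the ligand Tgfb1 by 0.98 (SE 0.11), while Ccn2, a secreted target of the pathway, fell by 1.55. Among proteases and inhibitors Adamts5 rose by 1.06 and Timp1 fell by 0.85, with 16 of 18 not past the test (camera adjusted p = 0.76).

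**Figure D3:**
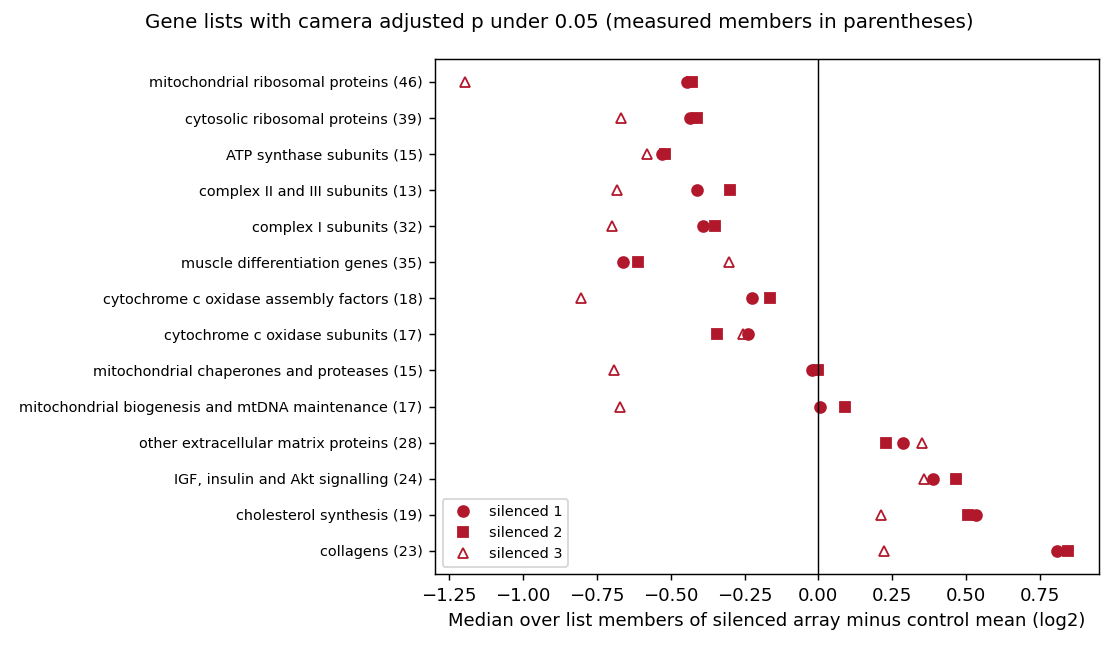
For the 14 gene lists with a camera adjusted p under 0.05 (vertical axis, measured members in parentheses), the median over members of each silenced array's log2 signal minus the control mean (horizontal axis), with filled circles and squares for silenced replicates 1 and 2 and open triangles for silenced replicate 3. Mitochondrial ribosomal proteins lie at -0.44, -0.43 and -1.20, and collagens at 0.81, 0.85 and 0.22.

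Of 19 glycolysis genes 2 rose and 1 fell with all arrays (camera adjusted p = 0.33). Aldoc, an aldolase, rose by 0.77 (SE 0.15, adjusted p = 0.032) and Pkm, pyruvate kinase, by 0.53, from a high level of 12.87, while Ldha, a lactate dehydrogenase subunit, fell by 0.59. Without silenced replicate 3, 11 rose and 2 fell, and the camera adjusted p was 0.013 (adjusted p = 0.32 with an estimated correlation). In glucose and monocarboxylate transport 2 of 13 passed as higher, Slc16a7 (1.04) and Slc2a12 (0.66), and 0 fell (2 lower at an unadjusted p under 0.05; camera adjusted p = 0.13). The signals of Slc2a12 lay within the range of receptor genes in each array, and so did the control signals of Slc16a7. Expression of Slc2a12 is therefore not shown, and the size of the Slc16a7 difference is not resolved. Of genes of pyruvate dehydrogenase and the citric acid cycle 3 of 23 rose, namely Pcx, pyruvate carboxylase (1.62, SE 0.23, adjusted p = 0.013), Pdk2, a kinase that inhibits pyruvate dehydrogenase (0.89), and Ogdh (0.77). None fell (5 lower at an unadjusted p under 0.05; camera adjusted p = 0.44). Without silenced replicate 3 the transport and citric acid cycle lists were called, at camera adjusted p = 0.028 and 0.049 (adjusted p = 0.37 and 0.39 with an estimated correlation), with 8 and 12 that rose and 2 and 5 that fell.

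In the pentose phosphate pathway Pgd rose by 0.82 and Tigar fell by 0.87 (1 and 1 of 8, camera adjusted p = 0.44). Of 16 genes of pyrimidine synthesis and uridine salvage 2 fell, Tyms, thymidylate synthase (-1.02), and Upp1, a uridine phosphorylase (-0.71), with camera adjusted p = 0.068, while 4 rose and 6 fell without silenced replicate 3. In fatty acid oxidation Cpt2 rose by 0.78 and Echs1 fell by 0.76, with 16 of 18 not past the test (camera adjusted p = 0.23). Genes of cholesterol synthesis rose in 6 of 19 cases and fell in 0 (12 higher and 0 lower at an unadjusted p under 0.05). They included Lss, lanosterol synthase (1.46, SE 0.27, adjusted p = 0.026), the transcription factor Srebf2 (1.09, SE 0.12), Dhcr7 (0.68) and Nsdhl (0.61), and 10 rose when adjusted over the list alone. The list had camera adjusted p = 0.00031, and adjusted p = 0.32 with an estimated correlation, and without silenced replicate 3, 12 rose and 3 fell.

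Of the IGF, insulin and Akt list 4 of 24 rose and 0 fell (12 higher and 0 lower at an unadjusted p under 0.05), namely the receptor Igf2r (1.47, SE 0.34, adjusted p = 0.048), Foxo1 (1.21), Tsc2 (0.69) and Igfbp7 (0.50), with camera adjusted p = 0.00020 and adjusted p = 0.35 with an estimated correlation. In this list 16 rose and 2 fell without silenced replicate 3. Among the named members, Foxo1 and Tsc2 are known as targets that Akt inhibits. In the calcium and calcineurin list 3 of 26 rose, Ppp3ca, a catalytic subunit of calcineurin (0.80), Nfatc1 (0.76) and Atp2b4 (0.72), and 2 fell, with Casq2, which binds calcium in the sarcoplasmic reticulum, at -1.66 (camera adjusted p = 0.15). The list was called without silenced replicate 3, with 13 that rose and 4 that fell (camera adjusted p = 0.017; adjusted p = 0.24 with an estimated correlation). Of NF-kappa B and retrograde signalling factors 1 of 17 rose, Egr1 (0.47), with camera adjusted p = 0.47, and 6 rose and 2 fell without silenced replicate 3. Among hnRNP proteins Hnrnpul1 rose by 0.96 and Hnrnpdl fell by 0.78 (2 higher and 1 lower of 17, camera adjusted p = 0.54). The probe set of Hnrnpu with the highest mean signal was 0.48 higher, whereas the mean of its probe sets gave -0.64 (adjusted p = 0.087), so its direction depends on the probe set.

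Of 30 targets of ATF4, the factor of the integrated stress response, 1 rose, Vldlr (1.15), and 2 fell, Atf3 (-1.20) and Nupr1 (-0.58), with camera adjusted p = 0.47. Silenced replicate 3 had a median of -0.64 on this list, against 0.17 and 0.19 in silenced replicates 1 and 2, and without it 14 rose and 6 fell. Of 17 targets of NRF2 the glutathione transferases Gstm2 (1.28, SE 0.19) and Gstm1 (1.02) rose and 0 fell (0 lower at an unadjusted p under 0.05; camera adjusted p = 0.18). This list too was called without silenced replicate 3, with 8 that rose (camera adjusted p = 0.0033; adjusted p = 0.23 with an estimated correlation). Of 14 other antioxidant enzymes Sod3 rose by 0.85, and Prdx4 and Gpx1 fell by 0.82 and 0.76 (camera adjusted p = 0.18). Of the hypoxia list 3 of 23 rose, Ndrg1 (1.35), Egln3 (0.77) and Plod2 (0.56), and Ldha fell (camera adjusted p = 0.79). Its median was -0.37 in silenced replicate 3 and 0.40 and 0.49 in silenced replicates 1 and 2, and without silenced replicate 3, 13 rose and 5 fell. Sel1l (0.77) was the called member among 17 chaperones of the endoplasmic reticulum and Bag3 (1.00) among 11 heat shock proteins (camera adjusted p = 0.95 and 0.42), with 6 and 4 that rose and 3 and 1 that fell without silenced replicate 3. Among 22 p53 targets Fas rose by 0.82 while Tigar and Ei24 fell by 0.87 and 0.59 (camera adjusted p = 0.47), and 9 rose and 4 fell without silenced replicate 3. Of 19 apoptosis regulators 0 passed limma's test (2 at an unadjusted p under 0.05; fry adjusted p = 0.74, and 0.32 for changes in either direction), and the largest difference was in Bad, at -0.54 with an adjusted p of 0.051, and 4 rose and 1 fell without silenced replicate 3.

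In the G1 to S list 4 of 33 fell, Gins2 (-1.33), the cyclins Ccnd2 (-1.22) and Ccne1 (-0.96), and Pcna (-0.48), and 0 rose (3 higher at an unadjusted p under 0.05; camera adjusted p = 0.47). Of these, 17 rose and 5 fell without silenced replicate 3, the list's median being -0.48 in that array and 0.21 and 0.23 in silenced replicates 1 and 2. In the G2 and mitosis list Cenpa (-1.02), Mad2l1 (-0.97) and Cdc25b (-0.79) fell and Mki67, the proliferation antigen Ki-67, rose by 0.61, of 31 measured (camera adjusted p = 0.073), and 11 fell and 6 rose without silenced replicate 3. Among cell cycle inhibitors Cdkn1b fell by 0.86 and Rb1 rose by 0.77, of 13 measured (camera adjusted p = 0.71). Of 24 lysosomal genes 3 rose, with Gaa, acid alpha-glucosidase, first (1.49, SE 0.11, adjusted p = 0.0039), followed by Psap (0.66) and Tpp1 (0.62), and Gla fell by 0.58 (camera adjusted p = 0.53). Of 28 adhesion genes 5 rose, among them Cdh2, N-cadherin (1.06), Ncam1 (0.96) and Itgb5 (0.82), and Cd44 fell by 1.07 (camera adjusted p = 0.71). Without silenced replicate 3, 7 adhesion genes rose and 6 fell. In the list of epithelial-mesenchymal transition Cdh2 and Tcf4 (0.92) rose, and Krt19 (-0.76) and Foxc2 (-0.73) fell, of 15 measured (camera adjusted p = 0.99). Of 29 interferon-stimulated genes 3 rose, H2-K1 (0.97), Tap1 (0.86) and Rsad2 (0.85), and Irf9 fell by 0.61 (camera adjusted p = 0.061). Of 20 cytokines Csf1 (0.94) and Cx3cl1 (0.74) rose and Tslp fell by 0.93 (camera adjusted p = 0.91).

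Markers of other cell types gave no list called by camera among 7, the smallest camera adjusted p being 0.33, and of 75 measured members 3 rose and 4 fell. The adipocyte factor Cebpa rose by 1.45 (SE 0.14, 1 of 11), and fry called the adipocyte list higher (adjusted p = 0.00067, median 0.15). Of 11 macrophage and leukocyte markers Lyz2 was 0.81 higher, though within the range of receptor genes in each array, and Cd68 fell by 0.66. Of 10 neural markers Syt1 rose by 1.62 and Nefl fell. S100a4 of the fibroblast list and Krt19 of the epithelial list fell by 0.60 and 0.76. Of 12 osteoblast and cartilage and 10 endothelial markers 0 passed limma's test (2 and 0 at an unadjusted p under 0.05; fry adjusted p = 0.77 and 0.74). Fry's test for changes in either direction passed for 36 of the 50 lists, 5 of them marker lists, at adjusted p = 1.9e-06 (neural), 0.0022 (epithelial), 0.0085 (adipocyte), 0.0099 (osteoblast and cartilage) and 0.043 (macrophage), and missed for the fibroblast (0.13) and endothelial (0.71) markers. The largest differences in the osteoblast and cartilage list were 0.58 in Phex and -0.48 in Sox9. In the endothelial list they were 0.25 in both Pecam1 and Cdh5. Markers that rose without silenced replicate 3 numbered 4 (adipocyte), 1 (osteoblast and cartilage), 2 (fibroblast), 1 (macrophage), 0 (endothelial), 2 (neural) and 3 (epithelial). In the same order 1, 1, 1, 1, 0, 3 and 2 fell. In silenced replicate 3 the medians of the endothelial, macrophage, fibroblast and adipocyte lists lay 0.39, 0.38, 0.45 and 0.34 above the controls, against -0.025, -0.053, -0.047 and 0.12 in silenced replicate 1. Olfactory and vomeronasal receptor genes, 1405 probe sets, had a median of 0.75 above the controls in silenced replicate 3 and of -0.043 in silenced replicate 1.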

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

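All tests in this part other than the fit over all probe sets were chosen after the results were seen.

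Probe sets that the annotation does not list stay out of the comparison of named genes, and a signal appeared there too. When all 41345 probe sets were fitted with limma, 244 of the 16004 unlisted ones were higher in silenced arrays and 1841 were lower at an adjusted p under 0.05. Of the lower ones, 1352 lay in a block of 5333 probe sets whose identifiers precede those of the first listed probe set, against 2 higher ones there. The median signal of this block was 6.08, 6.21 and 6.11 in silenced replicates 1, 2 and 3 and 6.75, 6.89 and 6.84 in control replicates 1, 2 and 3, and 88.3% of the block was lower in the silenced mean. The other 10671 unlisted probe sets had a median difference of 0.043.

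What this block measures is not given in the sources used here, and it follows the group in all 6 arrays. A trend with signal level argues poorly for it, since the block fell by 0.67 log2 more, at the median, than listed probe sets of the same control level (interquartile range of that difference 0.81). Genomic DNA carried over in the control samples would also raise 1405 olfactory and vomeronasal receptor probe sets there, but their median difference was 0.24, and -0.043, -0.013 and 0.75 in silenced replicates 1, 2 and 3. A candidate explanation that stays open is less RNA derived from introns in the silenced cells. Small nucleolar RNAs, which are cut from introns, had median differences of -0.87, -0.75 and -1.01 in silenced replicates 1, 2 and 3, but without the identity of the block this decides nothing, and silencing, pyruvate and uridine cannot be told apart as its origin.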

How the results depend on the processing

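The alternatives with silenced replicate 3 alone, corrected for its level trend, left out with a 2-fold limit and left out with an estimated correlation were chosen after the data were seen, as was the reading of the other splits. Cox4i1 was lower under each of the 15 alternatives for which it was fitted, and none of the 14 called lists reversed. Of the named genes, Hnrnpu reversed, at -0.64 as the mean of its probe sets, and the cause was not tested. The median of all listed probe sets stayed within 0.1 log2 of 0 under each scaling. The count of called probe sets, by contrast, moved with most choices, and for these shifts the cause was not tested unless stated.

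With quantile normalisation applied again 3663 probe sets were called, 1600 of them higher, and 7 lists were higher. With each array centred on its median 412 were higher, and 40 of 150 called named genes other than Cox4i1 lost their call. As many as 138 did so with the replicate block, 147, 146 and 145 without control replicate 1, 2 and 3, and 99 and 69 without silenced replicate 1 and 2. Array weights gave 13712, with 6997 higher and 6715 lower, 9 lists higher and a Cox4i1 difference of -4.32 (adjusted p = 5.9e-08). The weights (18.4 for silenced replicate 1, 0.38 for silenced replicate 2 and 0.041 for silenced replicate 3) came from a fit that did not converge, so these counts carry little weight. Without probe sets of a mean under 6, Cox4i1 kept its -3.33 and passed the threshold (adjusted p = 0.045, within a range of 5.9e-08 to 0.20 over those 15), since fewer were tested. Silenced replicate 3 corrected for its trend with level gave 4184, with 2120 higher, and 8 lists higher. All deposited probe sets gave 4301, with 3257 lower, which includes the unlisted block. Stricter limits lower the count by construction, to 462 (148 higher, 314 lower) at an adjusted p under 0.01 and 745 (239 and 506) at 2-fold, and 1271 at 2-fold without silenced replicate 3, of which 493 were lower. Silenced replicate 3 alone against the controls gave 14790 (8019 higher, 6771 lower), with the spread taken from the controls alone.

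Leaving out each array in turn gave 3 to 9247 called probe sets, 0 to 4989 of them higher and 3 to 4258 lower, a Cox4i1 difference of -4.35 to -2.81 and 3 to 9 lists higher. The highest counts came without silenced replicate 3. The lowest came without a control, where 3, 5 and 6 were called without control replicate 1, 2 and 3. With an estimated correlation camera called 0 lists, 0 higher and 0 lower, with all arrays and also without silenced replicate 3 (7 and 10 at an unadjusted p under 0.05). Fry called 7 higher and 6 lower, 9 of them among the 14 lists.

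As a check of pairing by replicate number, the deviations of same-numbered arrays from their group means correlated at -0.070, 0.088 and -0.018. With each control, silenced replicates 1 and 2 correlated with the same sign and silenced replicate 3 with the opposite sign. Silenced replicate 3 thus weighs on all silenced deviations, and the check cannot decide whether the numbers pair the samples. With the replicate block 45 probe sets were called, 19 higher and 26 lower, and the 14 lists stayed at 14. Silenced replicate 2 correlated best with control replicate 2, its own number (0.088), but silenced replicate 1 also did (0.060) and silenced replicate 3 correlated best with control replicate 1 (0.097).

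There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split called 2229 probe sets in limma, and 1 of the 10 splits called as many, since the highest of the other splits was 0 (71 to 1298 at an unadjusted p under 0.05). For lists the real split called 14 and the highest other 19, and 9 of the 10 splits called as many or more. Detection of each probe set over its own background was not analysed here, so the limit for dim probe sets rests on the mean signal alone.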

Other observations

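The gene families below were chosen after their values were seen, and so were the tests of silenced replicate 3.

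Of 76 probe sets of small nucleolar RNAs, which guide the modification of ribosomal RNA, 38 fell and 0 rose in limma, with a median difference of -0.88, and 65 fell without silenced replicate 3. Of 18 probe sets of their non-coding host genes 12 fell and 0 rose, with a median of -1.28, and Snhg1 was 2.46-fold lower (adjusted p = 0.013). With quantile normalisation again 36 and 13 fell, and with centred arrays 35 and 11. Subunits of the proteasome fell in 11 of 41 cases, with a median of -0.45, and rose in 0 (1 with quantile normalisation again), and without silenced replicate 3, 26 fell and 3 rose. Translocase subunits of the mitochondrial inner membrane fell in 5 of 18 cases and rose in 0, with a median of -0.61, and without silenced replicate 3, 13 fell with a median of -0.40.

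Several genes had 1 level in silenced replicates 1 and 2 and another in silenced replicate 3. Bgn, the proteoglycan biglycan, had log2 signals of 7.44 and 7.59 in silenced replicates 1 and 2 but 13.44 in silenced replicate 3, near the controls at 12.87 to 12.93. Col1a1, a chain of collagen I, was at 11.27, 11.28 and 8.22 against 8.60 to 8.73, and Rhox5, an X-linked homeobox gene of the germ line, at 11.15, 11.11 and 7.01 against 6.98 to 7.17. Conversely Pax7, a factor of muscle satellite cells, was at 7.80, 7.85 and 10.10 against 8.18 to 8.23, and Mest at 6.96, 6.90 and 11.03 against 8.70 to 8.88. Myf5, a myogenic factor, was lower in silenced replicate 3, at 8.09, than in silenced replicates 1 and 2 (10.96 and 11.02) and the controls (10.45 to 10.68).

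For silenced replicate 3 as a whole, a trend with signal level is part of the difference but argues poorly as its only source. Removing the trend took away 32.7% of the variance of its differences from the other 5 arrays, and the SD left, 0.604, was 1.59 times the largest of the other arrays, 0.380. The same response at a weaker silencing, which Cox4i1 at 10.47 might point to, may be part of it. The shifts of silenced replicate 3 followed those of silenced replicates 1 and 2 with an r of 0.27 and a slope of 0.43 over all named probe sets. Across those shifted at least 2-fold r was 0.72 (across genes, which are not independent). Both sets of shifts were taken from nearly the same control signals, which alone can make them correlate, so these values do not decide it. As the only source, a weaker silencing would place most of the array's differences along the shift of silenced replicates 1 and 2. Silenced replicate 3 was set against control replicates 2 and 3, and silenced replicates 1 and 2 against control replicate 1. Yet 7.36% of the variance of its differences lay along that shift (10.6% after the trend was removed). Between silenced replicates 1 and 2, with controls split in the same way, the share was 79.7%. Whether the array is unrelated to the silenced cells cannot be decided from these shifts. Of 1302 probe sets shifted at least 2-fold in silenced replicates 1 and 2, 80.3% moved the same way in silenced replicate 3. After the trend was removed the share was 78.0%, where unshifted probe sets of the same level would give 55.0% (48.6%). But the controls correlated at 0.996 to 0.997, so both sides were set against nearly the same control signals. Probe sets with unusual control signals would shift the same way in any array unlike the controls. Another clone or culture and poorer RNA or hybridisation remain open and untested. The RNA integrity limits in the labels count up from sample to sample and were not used.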
